A study of Mus musculus with 6 samples.

How the data were processed

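RNA was measured by sequencing in 6 libraries from formaldehyde-crosslinked chromatin of MEL cells, a mouse erythroleukemia line. The 3 groups of 2 libraries each were the input chromatin, the chromatin captured with the masked TH59-DB probe, which the labels name as the negative control, and the chromatin captured with TH59-DB. The libraries were made with a stranded total RNA kit. The labels number only the second library of each group, so the library without a number was taken as number 1. Nothing in the labels says whether the libraries of a group came from separate cultures, so every p-value measures only the spread between these libraries.

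The deposited files hold counts, which are whole numbers of reads per assembled transcript model. They also hold FPKM values made by the authors, equal to the count divided by the model length and by a library total. The submitters' notes name cutadapt, HISAT2, Cufflinks and featureCounts, without versions or roles, and the mouse build mm10. A count of 0 was deposited with the FPKM of 1 read in the input libraries, masked TH59-DB 2 and TH59-DB 2, and as 0 in masked TH59-DB 1, so all computations used the counts. The library totals recovered from the FPKM values were 2985229 and 2854992 reads in the input, 1970838 and 3122558 in masked TH59-DB, and 1803723 and 2589100 in TH59-DB. The counts of the models summed to 1546653 and 1295431, 1363747 and 1341694, and 1063354 and 924636 reads in the same order. What the totals count is not stated in the files. CPM below means reads per 1000000 of these totals.

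Every file held the same number of models. The files of library numbers 1 and 2 name them differently; 7695 were matched on all exons and 264 on chromosome, first start and length, and 0 were left unmatched. No model had fewer than 5 reads in TH59-DB 1, unlike in the other libraries. The models may have been chosen from that library, which bears on every comparison with it. Model lengths ran from 36 to 7543 bases with a median of 257, and 5997 models had 1 exon. Exonic overlaps joined them into 7853 clusters, here called loci, and 208 models overlapped another, so reads of overlapping models can be shared. Genes were assigned from a RefSeq table of GRCm38.p6, which holds gene spans and no exons: a model was given a gene when at least 50% of its bases lay in the span. A gene of at most 1000 bases, such as a snoRNA, was given a single-exon model at most 8 times its length that covered it. In this way 6852 models fell in a span, of 4213 genes, and 1107 in none. A model in a span need not belong to that gene's transcript. The strand setting of the counting is unknown: of 9 overlapping pairs on opposite strands, 5 to 7 per library had counts within 10% of each other, so sense and antisense reads were not told apart. The rule for short genes was set after the files were seen, because without its length limit host-gene models took snoRNA and scaRNA names, and the scaRNA result rests on it.

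No genome sequence was at hand, so telomere repeats were not searched in any model, the planned list of genes holding such repeats was not run, and true chromosome ends are not known. As a stand-in, the distal mark of a chromosome was the end of its outermost gene or model, and the distance of each locus to it was used. The planned list of genes near the chromosome ends was applied to loci within 1 Mb and within 3 Mb of this mark. A list of loci in no gene span was added after the data were seen.

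Counts were tested with edgeR 4.0.16 (filterByExpr, TMM factors, glmQLFit with robust estimation, quasi-likelihood F-tests) in R 4.3.3, with 1 fit of all 6 libraries and a group term. This kept 5385 models, and the biological coefficient of variation was 0.702. A model passed at a Benjamini-Hochberg adjusted p under 0.05, and all tests were 2-sided. Fold changes are log2 values with their standard error (SE). Group levels are means of 2 libraries with their SD. Where a group had 0 reads in both libraries, the ratio was taken against 3 reads per library and is written as at least that fold. Otherwise ratios are of mean CPM, with a 95% exact binomial interval of the pooled reads where few reads were counted. These intervals cover counting error only, because the reads carry no molecular identifiers. Shares of reads or loci have 95% exact (Clopper-Pearson) intervals.

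Lists of genes were tested with camera in limma 3.58.1 on log2 values, with a preset correlation of 0.01 and again with an estimated correlation, and with fry, when at least 3 members were measured; Benjamini-Hochberg adjustment ran over the 23 lists of each comparison. The lists were written before the data were examined: named fixed genes, telomerase and shelterin, nuclear lncRNAs, snoRNA host genes, snoRNAs, scaRNAs, spliceosomal and small polymerase III RNAs, ribosomal RNA precursors, mitochondrially encoded genes, ribosomal protein, histone and translation-factor genes, erythroid genes, markers of other blood cells and of other tissues, abundant cytoplasmic mRNAs, secretory and membrane mRNAs, long genes, mRNAs known for retained introns, zinc-finger (Zfp) genes, antisense-named genes, and annotated protein-coding and lncRNA genes. Protein-coding symbols that only look like antisense names were taken out of that list afterwards. Each gene was represented by its most abundant model.

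Genes were named by a rule set before the data were examined. For each comparison it took up to 10 models higher and 10 lower with the largest fold change among those past the threshold, of the same sign in both same-numbered pairs and with a mean of at least 5 CPM in the higher group; where fewer passed, the smallest p filled the list. The fixed genes and the members of each list with the highest, the lowest and the most abundant value were added. Models named outside this rule are said to have been chosen after their values were seen.

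The correlation of both captures' fold changes over the shared input was set beside 100 simulations of unchanged groups. Agreement of library numbers 1 and 2 was computed on log2(CPM + 0.5) differences across models, which are not independent replicates. The procedure was tested on simulated data with 5385 models and 10 rounds: 37.2% of 16-fold changes (339 of 911) and 3.36% of 4-fold changes were called, and 4.4% of the calls counted were false. Calls in a list shifted for the list test were not counted. The simulated counts had neither the read floor of TH59-DB 1 nor the many zeros of masked TH59-DB 1, so these shares may not hold for the real libraries.

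Alternatives set before the data were examined were a replicate block, leaving out each library, only the groups compared, no filter, at least 5 CPM in 2 libraries, DESeq2 1.42.0 size factors and its Wald test, removal of structural RNA and mitochondrial models, an estimated list correlation, crossed input libraries and quantile normalization for the agreement. Library totals without TMM, totals without the 2 largest models, 1 model per overlapping cluster, and all settings of the count of loci near the distal mark were chosen after seeing the data. The planned pseudocounts and the quantile normalization of the tests were for deposits with normalized values only and were not used. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.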

Results

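RNA bound to chromatin was sequenced after capture with TH59-DB, a pyrrole-imidazole polyamide probe directed at telomeres, in crosslinked MEL cells, which are mouse erythroleukemia cells. The 6 libraries comprised 2 of input chromatin, 2 of capture with the masked probe, the negative control, and 2 of capture with TH59-DB. Library totals ran from 1803723 to 3122558 reads, and 35.7% to 69.2% of them lay in the deposited transcript models. A single read was thus 0.320 to 0.554 CPM (reads per 1000000 of the library total). Across models, the Spearman correlation was 0.901 between the input libraries, 0.595 between the masked libraries and 0.602 between the TH59-DB libraries. The libraries did not group by capture alone. Masked TH59-DB 2 had 0.780 with input 1, 0.801 with input 2 and 0.626 with TH59-DB 2, each above its value with masked TH59-DB 1. Masked TH59-DB 1 had 0.546 with input 1 and 0.528 with input 2.

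The libraries differed in composition. A model of 414 bases in the span of Zc3h7a (chromosome 16, 11143911 to 11144324), named after its values were seen, held 50.8% of masked TH59-DB 1 (95% exact interval 50.7% to 50.8%) and 2.77% of TH59-DB 2 (2.75% to 2.79%). In masked TH59-DB 1, 4341 models had 0 reads, against 1404 to 1884 in the input libraries, masked TH59-DB 2 and TH59-DB 2. In TH59-DB 1 no model had fewer than 5 reads, and 99.3% had at least 10, against 30.3% to 58.7% in the other 5 libraries.

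The comparison of TH59-DB with masked TH59-DB asks which RNAs the telomere-directed probe brought down beyond the control probe. Terc, the RNA template of telomerase (chromosome 3, 96414374 to 96414859), was 363-fold higher. It made up 2.26% ± 1.23 of the TH59-DB reads, 0.00624% ± 0.00208 of the masked reads and 0.00287% ± 0.000685 of the input (SD, n = 2 each). Of 291 loci within 1 Mb of the distal mark of a chromosome, its outermost gene or model, 154 passed the read filter and were tested. A locus near 0 in the other groups could pass the filter only through both TH59-DB libraries, which favours higher values. Of the 154 tested, 12 passed as higher and 142 did not pass. As a list they lay above the other models (camera adjusted p = 4.48e-21, and adjusted p = 0.346 with an estimated correlation). Loci within 10 kb of the mark made up 1.88% ± 1.83 of TH59-DB, 0.0285% ± 0.00915 of masked TH59-DB and 0.000395% ± 8.51e-05 of the input (SD, n = 2 each). One model on chromosome 2 held most of these reads in both captures, and without it the shares were 0.344% ± 0.237, 0.00836% ± 0.00389 and 0.000241% ± 5.60e-05. The mRNAs of ribosomal proteins lay below the other models (camera adjusted p = 1.56e-16, and adjusted p = 0.533 with an estimated correlation).

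**Figure D1:**
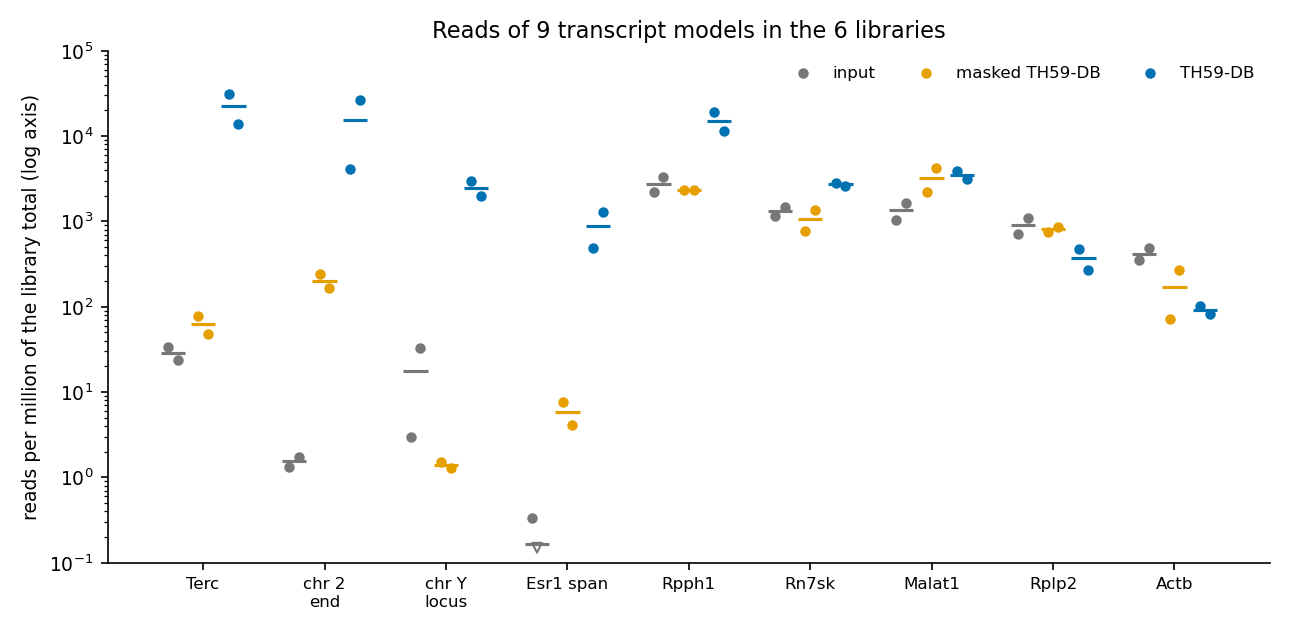
CPM (log axis) for 9 transcript models, with 1 point per library and a bar at the mean of each group of 2; an open triangle marks 0 reads. Terc averaged 62.4 CPM in masked TH59-DB, and both TH59-DB libraries lay above 10000 CPM, while Malat1 and Actb did not pass the test.

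In this comparison 76 models at 64 loci were higher in TH59-DB and 0 were lower (edgeR, adjusted p under 0.05); at an unadjusted p under 0.05 the counts were 445 higher and 91 lower, and DESeq2 called 266 higher and 1 lower. Terc passed with a log2 fold change of 8.50 (SE 1.44, adjusted p = 0.0248), in both same-numbered pairs of libraries. Its counting interval was 319-fold to 401-fold (pooled ratio 357). The adjusted p was 0.0901 without masked TH59-DB 1 and 0.0519 without masked TH59-DB 2, the only 2 of 16 alternatives that ended the call (range 1.97e-25 to 0.0901).

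Of 10 models named for their fitted fold changes, 2 lay near the distal mark of chromosome Y. All but 1 of the 10 had 0 masked reads, so their order hung on how 0 reads were fitted, and for these only a lower bound of the fold is given. The model from 90813197 to 90821200 had 2484 CPM ± 738 in TH59-DB and 1.40 ± 0.171 in masked TH59-DB (SD, n = 2). Its ratio was 1772 (pooled ratio 1739, counting interval 844 to 4327, log2 fold change 10.94, adjusted p = 0.0148). The model from 90811027 to 90811230, 32.7 kb from the mark, was at least 104-fold higher, with 0 masked reads (adjusted p = 0.0148). On chromosome 2, 141 kb from the mark, the model starting at 181870889 was at least 48.1-fold higher (adjusted p = 0.0197). Farther from the marks, a model in the span of Nedd4l, a ubiquitin ligase gene, was at least 68.4-fold higher (adjusted p = 0.0148). So were models in the spans of Bod1, a gene of chromosome biorientation (at least 41.2-fold, adjusted p = 0.0332), Gm30751 (at least 44.4-fold, adjusted p = 0.0431) and Gm14325 (at least 30.5-fold, adjusted p = 0.0248). Loci in no gene span were higher on chromosome 6 from 147236646 (at least 47.3-fold), chromosome 5 from 32629166 (at least 58.8-fold) and chromosome 9 from 90512709 (at least 34.2-fold). Without TH59-DB 2, the adjusted p was 0.244 for Gm30751, Bod1, Gm14325 and the chromosome 6 locus, and 0.172 for the chromosome 2 locus. For the chromosome 9 locus it was 0.0952 without TH59-DB 2 and 0.0789 without TH59-DB 1. Over all alternatives the adjusted p of these 6 models ran from 2.02e-08 to 0.325.

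No model passed as lower. The smallest p in that direction belonged to models in Ybx3, a cold-shock domain protein gene (log2 fold change -2.87, adjusted p = 0.105), and Tet3, which oxidises methylcytosine (-2.43, 0.144). They were followed by Rasa1 (-2.91, 0.173), Akt1 (-2.15, 0.184), Rpia (-2.20, 0.195) and Gpi1 (-2.06, 0.205). The last were Minpp1 (-2.00, 0.219), Mrpl12 (-2.44, 0.220), Cox4i1 (-1.87, 0.225) and Kdm3a (-2.78, 0.233).

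Of the 20 fixed genes, 9 had a model, and only Terc passed, also when adjusted over the list alone. Rpph1, the RNA of RNase P, made up 1.52% ± 0.548 of TH59-DB and 0.233% ± 0.00165 of masked TH59-DB reads (SD, n = 2), with a log2 fold change of 2.83 (SE 1.05, adjusted p = 0.314). The values were 1.67 for Rn7sk (adjusted p = 0.679), 1.20 for Rmrp (0.790), 1.26 for Kcnq1ot1 (0.754) and 0.43 for the nuclear lncRNA Malat1 (0.972), which was -0.25 with totals without the 2 largest models and -0.12 without TH59-DB 2. They were -0.41 for the erythroid factor Gata1 (0.966), -0.52 for Actb (0.951) and 1.95 for Gapdh (0.872), which had 0 reads in masked TH59-DB 1. Gata1 turned to 0.27 without TH59-DB 1, and Actb to 0.01 without masked TH59-DB 2.

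By position, 41 of the 76 models lay in no gene span (8.13% of 504 tested against 0.717% of the rest, Fisher's exact test p = 3.56e-23), 26 in spans of protein-coding genes and 8 in spans of lncRNA genes. No model had fewer than 5 reads in TH59-DB 1, so loci held only by the other libraries could be missing from the set, and these shares hold only for the models deposited. Within 1 Mb of a distal mark lay 16 of them (9.94% of 161 tested against 1.15%, Fisher's exact test p = 4.44e-10). These were at 13 loci. Without chromosome Y 8 remained (5.97% of 134 against 1.29%, Fisher's exact test p = 5.41e-04). The count of 16 was 94 without masked TH59-DB 2, 62 without masked TH59-DB 1, 33 without input 1, 31 without input 2, 23 without TH59-DB 1 and 8 without TH59-DB 2. Overlapping models share reads, so they are not independent. Of 291 loci within 1 Mb 154 were tested, and those near 0 in the other groups only through reads in both TH59-DB libraries. As a list, 12 of the 154 tested loci were higher over all models, 62 were when adjusted over the list alone, and 0 were lower. Their median log2 fold change was 3.25 above that of all models (camera adjusted p = 4.48e-21, and adjusted p = 0.346 with an estimated correlation). Unshifted it was 3.56, and 2.70 with the 39 loci at 0 reads in a group set to their bound. Within 3 Mb, 15 of 313 loci were higher and 35 were when adjusted over the list alone. Their median was 0.78 above all models (camera adjusted p = 3.67e-08, and adjusted p = 0.533 with an estimated correlation). Both shifts were called without each library. The medians of 3.25 and 0.78 were 5.11 and 1.77 without input 1, 4.98 and 1.76 without input 2, 5.32 and 1.98 without masked TH59-DB 1, 1.13 and 0.83 without masked TH59-DB 2, 3.26 and 0.89 without TH59-DB 1 and 3.69 and 1.23 without TH59-DB 2. Without masked TH59-DB 2 the median of all tested models was 5.10, against 0.30 as reported, and the relative medians of that setting are set against it.

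The most abundant model within 5 kb of each distal mark, its end model, was named after the values were seen. Its abundance comes mostly from TH59-DB reads, so the choice itself favours higher values in TH59-DB. Of 16 tested end models, 4 passed and 12 did not (adjusted p = 0.0652 to 0.273). Those on chromosome 7 (from 145340841, at least 23.7-fold, adjusted p = 0.0499), chromosome 11 (121981510, at least 24.6-fold, 0.0340), chromosome 13 (120318425, at least 25.8-fold, 0.0369) and chromosome 17 (94886457, at least 28.5-fold, 0.0338) passed. These calls ended without TH59-DB 2 (0.244, 0.244, 0.244 and 0.177), and the last 3 also without TH59-DB 1 (0.132, 0.217 and 0.217). Over all alternatives their adjusted p ran from 4.29e-06 to 0.432. The end model of chromosome 2 (182012702 to 182013229) held 1.53% ± 1.59 of TH59-DB and 0.0202% ± 0.00526 of masked TH59-DB reads (SD, n = 2). Its ratio was 76.0, and it did not pass (log2 fold change 6.75, SE 1.58, adjusted p = 0.0704). Nor did those of chromosome 14 (25.5-fold, adjusted p = 0.105), chromosome 19 (log2 fold change 9.49, adjusted p = 0.0655) and chromosome 5 (5.57, 0.0652). With 1 library left out, log2 fold changes ran from 3.85 to 7.70 for chromosome 2 and 3.09 to 6.36 for chromosome 14. They ran from 4.55 to 14.74 for chromosome 19 and 2.90 to 7.01 for chromosome 5. Each was lowest without TH59-DB 2, and each passed in some of these settings. In library number 2 alone, 94.5% of 55 loci within 10 kb of the mark had a higher CPM in TH59-DB (95% exact interval 84.9% to 98.9%). The share was 85.3% of 75 loci from 10 to 100 kb, 44.7% of 161 from 100 kb to 1 Mb and 22.5% of 6486 over 10 Mb away. In library number 1 the median log2 difference was 3.92 within 10 kb and 3.22 to 3.66 beyond. With 4341 models at 0 masked reads, the 0.5 CPM offset can set it.

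**Figure D2:**
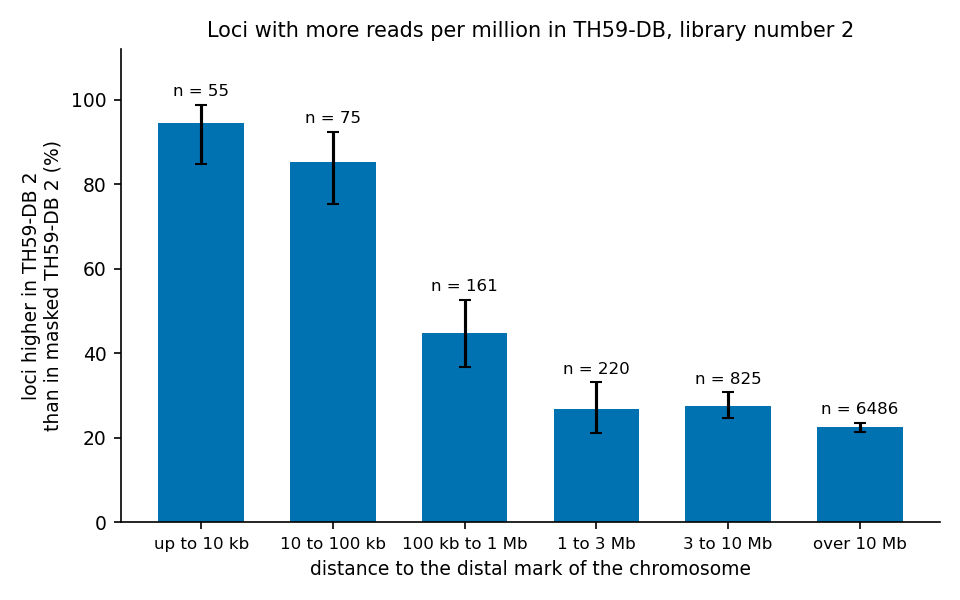
Percent of loci with a higher CPM in TH59-DB 2 than in masked TH59-DB 2 against the distance to the distal mark of the chromosome, with 95% exact intervals and the number of loci above each bar. The share was 94.5% within 10 kb and 22.5% over 10 Mb away.

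Of the telomerase and shelterin list, Terc alone passed of 6 tested (camera adjusted p = 0.297), and the shelterin protein gene Terf2 had -1.55 (adjusted p = 0.914). Of 11 long genes, 1 passed and 3 did when adjusted over the list alone. The model in Immp2l had a log2 fold change of 7.54 (adjusted p = 0.0332), while Mbnl1 had -0.85 and Gphn -0.71. Their median was 1.31 above all models (camera adjusted p = 0.0438, and adjusted p = 0.533 with an estimated correlation). All 5 scaRNAs, guide RNAs of Cajal bodies, had positive values, 0 passed over all models and 3 did when adjusted over the list alone. Scarna6 had 3.34, Scarna9 2.15 and Scarna17 1.75, and the median was 1.72 above all models (camera adjusted p = 0.0222, and adjusted p = 0.533 with an estimated correlation). The 6 small polymerase III RNAs also had positive values and 0 passed, from 2.83 for Rpph1 to 0.37 for the Y RNA Rny3. Their median was 1.34 above all models (camera adjusted p = 0.0438, and adjusted p = 0.533 with an estimated correlation). These 3 list shifts hung on single libraries. That of scaRNAs was kept only without TH59-DB 1 (1.44e-04, and adjusted p = 0.392 with an estimated correlation). It was lost without input 1 (0.136), input 2 (0.131), masked TH59-DB 1 (0.0633), masked TH59-DB 2 (0.754) and TH59-DB 2 (0.924). That of small polymerase III RNAs was lost without any one library (0.119, 0.123, 0.187, 0.847 and 0.915 in the same order, and 0.0593 without TH59-DB 1). That of long genes was lost without input 1 (0.0686), input 2 (0.0604), masked TH59-DB 2 (0.754) or TH59-DB 1 (0.151). Without masked TH59-DB 2 the values relative to all models are set against a median of all tested models of 5.10, against 0.30 as reported. Given in the order without input 1, input 2, masked TH59-DB 1, masked TH59-DB 2, TH59-DB 1 and TH59-DB 2, the medians relative to all models were 1.30, 1.29, 1.82, -2.99, 2.59 and -0.42 for scaRNAs. They were 0.80, 0.78, 1.05, -3.85, 1.56 and 0.24 for small polymerase III RNAs, and 5.20, 5.07, 5.61, 0.62, 0.74 and 1.76 for long genes.

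In 7 lists that lay below the rest, 0 members passed, over all models or adjusted over the list alone. Relative to all models, the median of 60 ribosomal protein genes was -1.17 (Rplp2 -0.98, Rps10 -1.95, Rps14 0.27, camera adjusted p = 1.56e-16). It was -0.87 for 21 abundant cytoplasmic mRNAs (Hsp90ab1 -0.56, Pfn1 -1.77, camera adjusted p = 1.13e-05) and -1.47 for 5 mitochondrially encoded genes (CYTB -2.45, mt-Rnr1 0.24, camera adjusted p = 0.00360). For 28 histone genes it was -0.61 (H2ac20 -0.31, H2ac6 -1.73, camera adjusted p = 0.00360) and for 16 translation factors -0.90 (Eef1a1 -0.95, Eif4a1 -2.22, camera adjusted p = 0.00615). For 18 secretory and membrane mRNAs it was -0.64 (Canx -0.47, Ssr3 -1.90, camera adjusted p = 0.0356), and for 25 mRNAs known for retained introns -0.58 (Srrm2 0.65, Ccnl2 -3.77, camera adjusted p = 0.0425). With an estimated correlation the adjusted p was 0.537 for the last and 0.533 for the other 6. Without TH59-DB 1 the unshifted medians of histones (0.20) and of retained-intron mRNAs (0.23) were positive, and that of ribosomal proteins was -0.30. The camera adjusted p was then 0.410, 0.525 and 1.38e-07. It was 0.151 for mitochondrial genes, 0.358 for translation factors, 0.151 for secretory mRNAs and 0.0482 for abundant cytoplasmic mRNAs. Without masked TH59-DB 2 it was 0.107 for mitochondrial genes, 0.0737 for translation factors, 0.447 for secretory mRNAs, 0.0847 for retained-intron mRNAs and 0.0479 for histones. Only the shifts of ribosomal proteins and abundant cytoplasmic mRNAs were called without each library. Without masked TH59-DB 2 the median of all tested models was 5.10, against 0.30 as reported, and values relative to it in that setting carry this rise. In the order without input 1, input 2, masked TH59-DB 1, masked TH59-DB 2, TH59-DB 1 and TH59-DB 2, the medians relative to all models were -1.62, -1.63, -1.57, -5.82, -0.56 and -2.52 for ribosomal proteins. They were -1.34, -1.37, -1.43, -5.40, -0.29 and -2.25 for abundant cytoplasmic mRNAs, and -1.91, -1.91, -2.12, -5.53, -0.83 and -3.02 for mitochondrial genes. Further values were -1.14, -1.15, -1.19, -5.0, -0.06 and -1.82 for histones, and -1.38, -1.38, -1.36, -4.87, -0.31 and -2.05 for translation factors. The next were -1.14, -1.15, -1.02, -5.03, -0.33 and -1.75 for secretory mRNAs, and -1.01, -0.99, -1.17, -4.47, -0.03 and -1.67 for retained-intron mRNAs.

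The 18 tested erythroid genes, markers of the cell line, had a median of -0.22 and a mean of 0.12 (Zfpm1 -0.89, Car1 -1.04, Car2 1.79), and 0 passed (camera adjusted p = 0.297). With DESeq2 size factors or without TH59-DB 1 the median was 0.03 or 0.05. Without TH59-DB 2 camera called a shift with the preset correlation but not with an estimated one. Both markers of other blood cells with a model, Itga2b and Laptm5, were tested and 0 passed (median 0.67). None of the 25 markers of other tissues had a model, and no model bore the symbol of a ribosomal RNA precursor. A locus in no gene span on chromosome 17, from 39842884, was taken as ribosomal from its position, and no sequence was at hand to test this. It held 6.83% ± 3.42 of TH59-DB, 7.46% ± 0.467 of masked TH59-DB and 8.28% ± 0.746 of input reads (SD, n = 2 each). No member passed and no shift was called for 6 nuclear lncRNAs (Kcnq1ot1 1.26, Tug1 -1.16, camera adjusted p = 0.943). Their median was 0.59 and their mean 0.31, and camera placed them below the rest. Nor did a member pass or camera call a shift for 6 snoRNA host genes (Snhg12 0.69, Snhg4 -1.14, Rack1 -0.69, camera adjusted p = 0.0906) and 21 snoRNAs (Snord13 3.45, Snora24 -0.47, Snord15a 0.50, camera adjusted p = 0.674). No member passed and no shift was called for 4 spliceosomal RNAs (Rnu11 2.40, camera adjusted p = 0.257), among which the list counts Rnu3a, the U3 snoRNA (0.42). Likewise there was no call for 64 Zfp genes (Zfp971 4.92, Zfp808 -2.26, Zfp292 0.92, camera adjusted p = 0.681) and 6 antisense-named genes (Atxn7l1os2 1.92, Peak1os -0.06, camera adjusted p = 0.304). Leaving out 1 library, medians relative to all models ran from -3.78 (without masked TH59-DB 2) to -0.21 (without TH59-DB 1) for erythroid genes and -4.47 (without masked TH59-DB 2) to 0.75 (without TH59-DB 1) for nuclear lncRNAs. Further ones ran from -6.14 (without masked TH59-DB 2) to -0.62 (without TH59-DB 1) for snoRNA hosts and -4.56 (without masked TH59-DB 2) to 0.22 (without TH59-DB 1) for snoRNAs. Others ran from -4.14 (without masked TH59-DB 2) to 1.09 (without masked TH59-DB 1) for spliceosomal RNAs and -1.26 (without masked TH59-DB 2) to 0.21 (without TH59-DB 1) for Zfp genes. Those ran from -0.39 (without masked TH59-DB 1) to 1.42 (without masked TH59-DB 2) for antisense-named genes and -4.55 (without masked TH59-DB 2) to 0.22 (without TH59-DB 2) for telomerase and shelterin. The values without masked TH59-DB 2 are set against a median of all tested models of 5.10, against 0.30 as reported.

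By annotation, 20 of 2771 protein-coding genes were higher and 8 were when adjusted over the list alone. Their median was -0.25 relative to all models (camera adjusted p = 2.78e-04, adjusted p = 0.533 with an estimated correlation, and 0.0612 without masked TH59-DB 2). Of 165 lncRNA genes 5 were higher, and 10 when adjusted over the list alone. Camera called no shift for these. With the preset correlation it did without input 1, input 2, masked TH59-DB 1 or TH59-DB 2, and with an estimated one in none of these settings. Of 477 loci in no gene span 32 were higher, and 100 when adjusted over the list alone, with the same limit of the read filter. Their median was 1.52 above all models (camera adjusted p = 1.24e-15, and adjusted p = 0.346 with an estimated correlation). For these groups, in the order without input 1, input 2, masked TH59-DB 1, masked TH59-DB 2, TH59-DB 1 and TH59-DB 2, the medians relative to all models were 2.90, 2.85, 3.48, 0.77, 1.47 and 2.13 for loci in no gene span. They were -0.41, -0.41, -0.34, -2.91, -0.21 and -0.40 for protein-coding genes, and 0.95, 0.96, 0.84, 0.60, 0.35 and 0.79 for lncRNA genes. Here too, the values without masked TH59-DB 2 are set against a median of all tested models of 5.10. By fry, which ignores unlisted genes, 5 lists moved on balance. They were long genes (adjusted p = 0.0111), loci within 1 Mb and in no gene span (0.0207 each), loci within 3 Mb (0.0488) and telomerase and shelterin (0.0488, Terc 8.50, median 0.45).

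**Figure D3:**
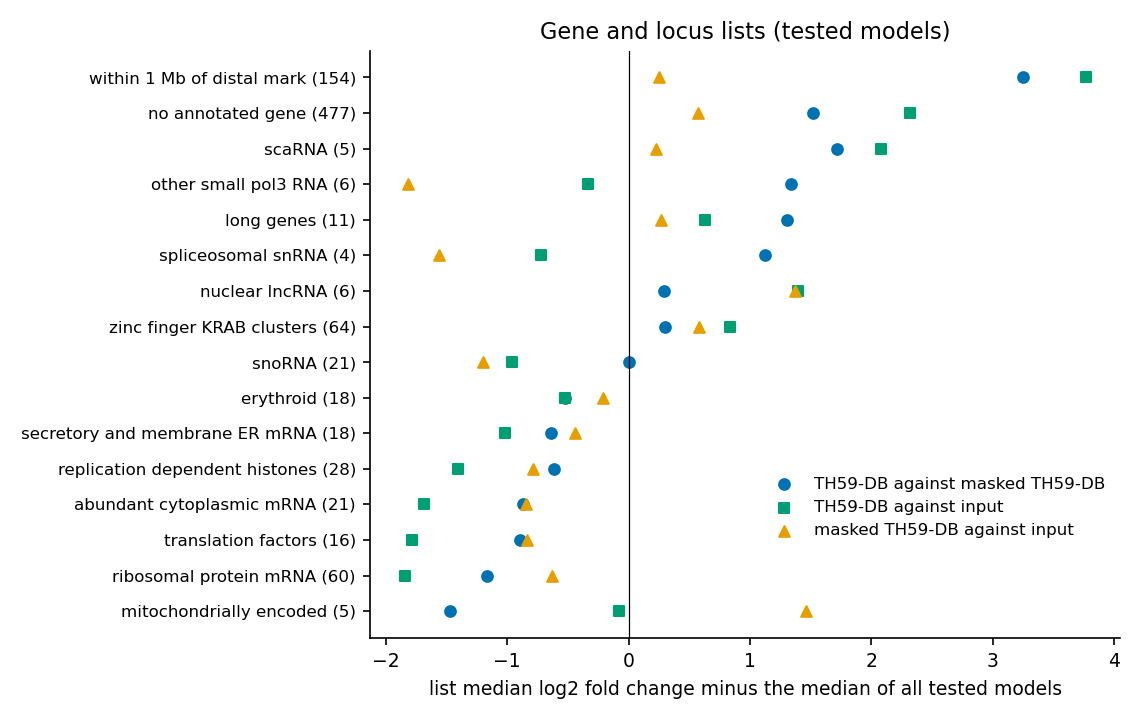
Median log2 fold change of each list minus the median of all tested models in the 3 comparisons, with the number of tested members in brackets. Loci within 1 Mb of the distal mark lay 3.25 above all models in TH59-DB against masked TH59-DB and 0.25 above in masked TH59-DB against input, where totals without the 2 largest models gave -0.21, and without TH59-DB 1 the mitochondrial value of TH59-DB against input turned from -0.08 to 0.54.

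The median of all tested models was 0.30 here, 0.51 with DESeq2 size factors and 0.08 with library totals. With totals without the 2 largest models it was -0.09, 132 models were higher and 29 lower, and the snoRNA median relative to all models turned from 0.01 to -0.09. The count of 76, all higher, was 1720 without masked TH59-DB 2 (1479 higher and 241 lower) and 313 without masked TH59-DB 1 (310 and 3). It was 148 without input 1 (147 and 1), 146 without input 2 (145 and 1), 136 without TH59-DB 1 and 32 without TH59-DB 2, all higher in the last 2. Of the 76 models, 31 were also called without TH59-DB 2, 64 without masked TH59-DB 1, 68 without TH59-DB 1, 74 without masked TH59-DB 2 and all 76 without input 1 or input 2.

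The comparison of TH59-DB with the input asks which RNAs the capture concentrated from the starting chromatin. Terc was 790-fold higher (log2 fold change 9.44, adjusted p = 0.00429, pooled ratio 733, counting interval 630 to 858). The end model of chromosome 2 was 9928-fold higher (pooled ratio 11264, counting interval 5933 to 24634, adjusted p = 0.00385). It had 68895 reads in TH59-DB 2 and 7357 in TH59-DB 1. Its log2 fold change was 10.55 without TH59-DB 2 and 14.87 without TH59-DB 1. Of 193 higher models at 157 loci, 85 had 0 reads in both input libraries and 149 had at most 3 together. A model of Gpi1, a glycolytic enzyme gene, was lower. The mRNAs of ribosomal proteins lay below the other models as a list (camera adjusted p = 6.38e-27, and adjusted p = 0.373 with an estimated correlation).

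Most models named for their fitted fold changes had 0 input reads, so only a lower bound of the mean fold is given and their order is open. One in the span of Ppp1r9a, which encodes an actin-binding neuronal protein, was at least 1574-fold higher (adjusted p = 0.00384). The end model of chromosome 19 (61331145 to 61331419) was at least 837-fold higher (adjusted p = 0.0173). The call ended without TH59-DB 2 (log2 fold change 9.77, against 15.91 without TH59-DB 1). Models in the spans of 2210408I21Rik (at least 695-fold, adjusted p = 0.00287), Gm35315 (at least 417-fold) and Pde1c, a phosphodiesterase gene (at least 274-fold, adjusted p = 0.00566), were also higher. Loci in no gene span were higher on chromosome 1 from 69456736 (at least 495-fold), chromosome 15 from 87967972 (at least 486-fold), chromosome 5 from 93289633 (at least 387-fold) and chromosome 8 from 71433020 (at least 381-fold).

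Lower were the models of the pseudogene Gm8730, whose reads can stem from a near-identical gene (log2 fold change -3.27, adjusted p = 0.0466), and of Gpi1 (-2.99, 0.0290). Gm8730 had an adjusted p of 0.828 without input 1, 0.231 without input 2 and 0.240 without TH59-DB 1 (range over the alternatives 1.38e-04 to 0.828). Gpi1 had 0.513 without input 1, 0.700 without input 2, 0.209 without TH59-DB 1 and 0.147 without TH59-DB 2 (range 0.00589 to 0.700). Not passing were Ybx3 (-3.02, 0.0613), Ddx46 (-2.83, 0.0649), the elongation factor Eef2 (-2.59, 0.0684) and Cox4i1 (-2.36, 0.0720). Nor did Gm15427 (-2.43, 0.0791), the histone gene H4c4 (-2.61, 0.0887) and a locus on chromosome X from 4136294 (-4.06, 0.0790). Of the 9 fixed genes only Terc passed, and 2 did when adjusted over the list alone. Kcnq1ot1, an imprinted lncRNA, had 3.04 (adjusted p = 0.0887), Rpph1 2.46 (0.299), Malat1 1.46 (0.584) and Rn7sk 1.13 (0.714). Gata1 had 0.28 (0.960, -0.96 without TH59-DB 2) and Actb -2.12 (0.215). Gapdh had 0.13 (0.986), which was -0.02 with library totals, -0.05 with totals without the 2 largest models, -0.65 without TH59-DB 2 and below 0 without input 1. Rmrp had -0.05 (0.991), which was 0.33 with DESeq2 size factors, 0.13 with library totals, 0.16 with totals without the 2 largest models and above 0 without input 1 or TH59-DB 1.

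Of the higher models, 103 lay in no gene span (20.4% of 504 tested against 1.84% of the rest, Fisher's exact test p = 1.52e-57). As every model had reads in TH59-DB 1 and 85 of the 193 had none in the input, this share may come from how the models were chosen. Within 1 Mb of a distal mark lay 26 (16.1% of 161 against 3.20%, Fisher's exact test p = 5.20e-11), and 17 without chromosome Y (12.7% of 134 against 3.35%, Fisher's exact test p = 4.63e-06). As a list, 20 of 154 tested loci within 1 Mb were higher and 59 were when adjusted over the list alone, with the same limit of the read filter. Their median was 3.77 above all models (3.80 unshifted, 2.99 with 30 loci at their bound, camera adjusted p = 1.15e-24, and adjusted p = 0.288 with an estimated correlation). Within 3 Mb, 24 of 313 were higher, and adjusted over the list alone 40 were higher and 1 lower. Their median was 1.12 above all models (camera adjusted p = 1.33e-08, adjusted p = 0.373 with an estimated correlation). In no gene span, 87 of 477 loci were higher, and adjusted over the list alone 158 were higher and 7 lower. Their median was 2.32 above all models (camera adjusted p = 8.26e-30, and adjusted p = 0.271 with an estimated correlation). Of 11 long genes 3 were higher (camera adjusted p = 0.106), and adjusted over the list alone 4 were higher and 1 lower. A model in Lrp1b was at least 147-fold higher (adjusted p = 0.00950), and Gphn had -4.06 (0.123). Of 165 lncRNA genes 12 were higher and 16 when adjusted over the list alone (median 0.72 above all models, camera adjusted p = 2.32e-04, and adjusted p = 0.373 with an estimated correlation). Of 2771 protein-coding genes 52 were higher and 1 lower, and 39 were higher when adjusted over the list alone (median -0.25, mean unshifted 0.17, camera adjusted p = 5.42e-05, and adjusted p = 0.424 with an estimated correlation). For these lists, in the order without input 1, input 2, masked TH59-DB 1, masked TH59-DB 2, TH59-DB 1 and TH59-DB 2, the medians relative to all models were 5.27, 4.85, 3.90, 3.93, 3.55 and 3.29 for loci within 1 Mb. They were 1.89, 1.86, 1.81, 1.82, 1.17 and 1.34 for loci within 3 Mb, and 5.05, 5.12, 3.42, 3.46, 2.27 and 3.09 for loci in no gene span. Further values were 0.56, 5.21, 0.99, 1.03, 0.84 and 1.97 for long genes, and 1.35, 1.20, 1.22, 1.12, 0.83 and 1.15 for lncRNA genes. The next were -0.46, -0.42, -0.43, -0.41, -0.19 and -0.42 for protein-coding genes.

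In the other lists no member passed, apart from Terc among the telomerase genes. Relative to all models the median was -1.85 for ribosomal proteins, with 0 of 60 positive (Rpl28 -2.49, Rpl36 -1.17, camera adjusted p = 6.38e-27). It was -1.41 for histones (H4c4 -2.61, H2ac10 -0.67, camera adjusted p = 3.62e-09) and -1.69 for abundant cytoplasmic mRNAs (Ybx1 -2.86, Hsp90ab1 -1.59, camera adjusted p = 2.87e-11). For translation factors it was -1.79 (Eef1a1 -2.75, Eif4a1 1.78, camera adjusted p = 6.13e-06) and for secretory and membrane mRNAs -1.01 (Ssr2 -1.97, Canx -0.63, camera adjusted p = 4.17e-04). For Zfp genes it was 0.84 (Zfp791 -4.50, Zfp292 1.92, camera adjusted p = 0.0172). Each of these 6 lists had an adjusted p = 0.373 with an estimated correlation. For snoRNAs the median was -0.96 (Snora73a -2.17, Snord15a -0.43, camera adjusted p = 0.0406, and adjusted p = 0.711 with an estimated correlation). For scaRNAs it was 2.08 (Scarna17 2.70, Scarna6 1.30, camera adjusted p = 0.0365, and adjusted p = 0.424 with an estimated correlation). The snoRNA shift was lost without input 1 (0.601) or TH59-DB 1 (0.174). The scaRNA shift was lost without each library except TH59-DB 1 (0.147 to 0.169, and 0.767 without TH59-DB 2), and that of Zfp genes without input 1 (0.103), input 2 (0.0787) or TH59-DB 2 (0.669). The other 5 were called without each library. For the same lists, in the order without input 1, input 2, masked TH59-DB 1, masked TH59-DB 2, TH59-DB 1 and TH59-DB 2, the medians relative to all models were -2.44, -2.25, -2.32, -2.28, -1.15 and -3.14 for ribosomal proteins. They were -1.84, -1.99, -1.85, -1.81, -0.73 and -2.50 for histones, and -2.32, -2.13, -2.15, -2.12, -1.05 and -3.29 for abundant cytoplasmic mRNAs. Further values were -2.23, -2.15, -2.21, -2.18, -1.07 and -2.93 for translation factors, and -1.50, -1.57, -1.52, -1.49, -0.48 and -1.93 for secretory mRNAs. The next were 0.82, 0.74, 0.60, 0.60, 0.89 and 0.67 for Zfp genes, and -0.27, -1.96, -1.49, -1.45, -0.53 and -1.71 for snoRNAs. The others were 1.88, 1.42, 1.73, 1.77, 3.21 and -0.01 for scaRNAs.

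Camera called no shift for telomerase and shelterin (adjusted p = 0.164, Nhp2 -1.12), snoRNA hosts (0.176, Snhg4 -2.63), spliceosomal RNAs (0.940, Rnu11 0.80) and small polymerase III RNAs (0.729, Rny3 -3.31). Nor did it for mitochondrial genes (0.501, ND6 0.54, CYTB -1.25), erythroid genes (0.0829, Car1 -2.34, Ppox 1.09), retained-intron mRNAs (0.284, Ddx5 -1.92, Ccnl1 1.27) and antisense-named genes (0.806, Rsf1os2 -0.71). For nuclear lncRNAs the adjusted p was 0.0715, Norad had 0.05, and 1 of 6 was higher when adjusted over the list alone. Spliceosomal RNAs (median -0.69, mean -0.49) and small polymerase III RNAs (median -0.31, mean -0.30) had negative values, while camera placed them above the rest. The median of the 2 blood markers was -0.70. With the preset correlation, shifts were newly called for erythroid genes without input 1, input 2, masked TH59-DB 1, masked TH59-DB 2 or TH59-DB 2. The same held for retained-intron mRNAs without input 1 or TH59-DB 2, long genes without TH59-DB 2 and spliceosomal RNAs without input 2. None of these shifts was called with an estimated correlation. Relative to all models and leaving out 1 library, medians ran from 0.40 (without input 2) to 1.67 (without TH59-DB 2) for telomerase and shelterin and -1.18 (without TH59-DB 2) to -0.48 (without input 2) for snoRNA hosts. Further ones ran from -2.18 (without input 2) to 1.23 (without input 1) for spliceosomal RNAs and -1.42 (without input 2) to 0.47 (without input 1) for small polymerase III RNAs. Others ran from -1.61 (without TH59-DB 2) to 0.54 (without TH59-DB 1) for mitochondrial genes and -1.35 (without TH59-DB 2) to -0.15 (without TH59-DB 1) for erythroid genes. Those ran from -1.38 (without TH59-DB 2) to -0.02 (without TH59-DB 1) for retained-intron mRNAs and 0.31 (without input 1) to 0.97 (without TH59-DB 1) for antisense-named genes. Further ones ran from 0.42 (without TH59-DB 2) to 1.96 (without TH59-DB 1) for nuclear lncRNAs. By fry, long genes, loci within 1 Mb and in no gene span (adjusted p = 0.0188 each) and telomerase and shelterin (0.0407, Terc 9.44) moved on balance.

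In the edgeR fit 193 models were higher and 2 lower, 477 and 277 were at an unadjusted p under 0.05, and DESeq2 called 369 and 28. With totals without the 2 largest models 212 were higher and 91 lower. The median of all models was 0.03, and 0.40 with DESeq2 size factors and 0.16 with those totals. The count of 195 was 708 without masked TH59-DB 1 (630 higher and 78 lower), 756 without masked TH59-DB 2 (689 and 67) and 102 without TH59-DB 2 (89 and 13). It was 149 without input 2 (136 and 13), 138 without input 1 and 185 without TH59-DB 1, all higher in the last 2. With a block it was 363 (245 and 118), with only the groups compared 497 (436 and 61) and with no filter 312 (287 and 25).

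The comparison of masked TH59-DB with the input asks what the control probe brought down. Few models passed: 14 at 9 loci were higher and 0 lower, and 10 of the 14 had at most 3 input reads. Of the 14, 7 lay in no gene span and 0 within 1 Mb of a distal mark. Yet loci within 10 kb of the mark together held more of the masked TH59-DB reads than of the input reads (0.0285% ± 0.00915 against 0.000395% ± 8.51e-05, SD, n = 2, and 0.00836% ± 0.00389 against 0.000241% ± 5.60e-05 without the chromosome 2 end model). Terc did not pass (2.18-fold, log2 fold change 0.94, SE 1.06, adjusted p = 0.893). Mitochondrially encoded RNAs (camera adjusted p = 0.0190) and nuclear lncRNAs (0.0142) lay above the other models as lists, and ribosomal protein mRNAs below them (1.17e-08), each with an adjusted p = 0.689 with an estimated correlation. None of the 3 shifts was called without masked TH59-DB 2 (0.433, 0.203 and 0.203). The mitochondrial median difference was -0.40 in library number 1 and 2.16 in number 2, and the mean share of these reads was not higher than in the input (1.11% against 1.38%).

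In no gene span, the called loci were on chromosome 10 (109396053 to 109422780, 1326-fold, pooled ratio 1305, counting interval 446 to 6332, adjusted p = 0.0312), chromosome 8 (71433020, at least 91.7-fold), chromosome 14 (95638412, at least 26.9-fold), chromosome Y (140526, at least 22.6-fold) and chromosome 2 (46225730, 457-fold). The others lay in the spans of Scn8a, a sodium channel gene (456-fold, pooled ratio 476, counting interval 84.9 to 18840), Setd4 (257-fold), Ttc21b (197-fold, pooled ratio 186, counting interval 32.9 to 7382) and Gm32035 (136-fold, pooled ratio 141, counting interval 47.8 to 685). Of the 16 tested end models 0 passed, 5 had positive values and 8 had 0 reads in both groups. Those of chromosome 2 (131-fold, log2 fold change 6.90, adjusted p = 0.157) and chromosome 14 (227-fold, 7.51, 0.127) had the most reads. Both passed with 9 of 16 alternatives, among them leaving out TH59-DB 1 (0.0392 and 0.0229), TH59-DB 2 (5.48e-05 and 3.34e-04) or masked TH59-DB 2 (0.0114 and 0.00278). A locus in Lama1, which encodes a laminin chain (1059-fold, counting interval 293 to 8746), did not pass (0.0524). All 14 calls ended without input 1 or without input 2, where 0 models passed (edgeR, 170 and 202 at an unadjusted p under 0.05). Over all alternatives the adjusted p of the 9 named models ran from 1.43e-17 to 0.388. Lower but not passing were loci on chromosome 2 from 98662237 (-4.36, adjusted p = 0.127), chromosome 7 from 99497728 (-5.66, 0.211) and chromosome 14 from 19417214 (-4.22, 0.359). The same held for loci on chromosome 4 from 149817729 (-4.57, 0.362) and chromosome 13 from 103396212 (-5.31, 0.364). It held for models in LOC115490001 (-5.20, 0.244), Lars2 (-3.82, 0.364), Zfp791 (-4.14, 0.377), Larp1 (-2.11, 0.377) and Zfp646 (at 0 reads in both masked libraries, adjusted p = 0.396). None of the fixed genes passed. They ran from Kcnq1ot1 (1.79, 0.732) and Malat1 (1.03, 0.854) through Gata1 (0.69, 0.902), Rpph1 (-0.37, 0.971, but 0.25 with totals without the 2 largest models and 0.22 without masked TH59-DB 2), Rn7sk (-0.54, 0.934, but 0.06 with those totals) and Rmrp (-1.25, 0.838) to Actb (-1.60, 0.748) and Gapdh (-1.82, 0.848).

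Camera called 10 lists here, each with an adjusted p = 0.689 with an estimated correlation, and 1 without masked TH59-DB 2. Relative to all models, the median was 1.37 for nuclear lncRNAs (Tug1 1.87, Norad 0.44) and 1.46 for mitochondrial genes (ND4 2.02, mt-Rnr1 -1.16). It was 0.58 for Zfp genes (Zfp292 1.00, camera adjusted p = 0.0190) and 0.44 for lncRNA genes (camera adjusted p = 0.00492), of which 1 of 165 was higher, also when adjusted over the list alone. For loci in no gene span it was 0.57 (camera adjusted p = 4.89e-09), with 5 of 477 higher, and 30 higher and 2 lower when adjusted over the list alone. It was -1.20 for snoRNAs (Snora61 -2.86, Snora65 0.05, camera adjusted p = 0.00252) and -0.63 for ribosomal proteins (Rplp0 -2.04, Rpl3 0.02). For histones it was -0.79 (H2bc14 -1.64, H2ac6 -0.20, camera adjusted p = 2.01e-05) and for translation factors -0.84 (Eif4g2 -2.08, Eif4a1 4.00, camera adjusted p = 0.00254). For abundant cytoplasmic mRNAs it was -0.85 (Actg1 -2.07, Pfn1 -0.26, camera adjusted p = 2.35e-05). Only the shift of loci in no gene span was called without masked TH59-DB 2. The others had 0.203 for nuclear lncRNAs, ribosomal proteins and histones, and 0.272 for abundant cytoplasmic mRNAs. They had 0.277 for snoRNAs, 0.433 for mitochondrial genes, 0.512 for translation factors, 0.244 for Zfp genes and 0.192 for lncRNA genes. Without input 1 the calls of snoRNAs (0.992), translation factors (0.0531) and Zfp genes (0.115) were lost. Without input 2 those of mitochondrial genes (0.0802), translation factors (0.0802), Zfp genes (0.0802) and lncRNA genes (0.0884) were lost. Without masked TH59-DB 1 those of translation factors (0.210), Zfp genes (0.0709) and lncRNA genes (0.162) were lost, and without TH59-DB 2 that of Zfp genes (0.0508). For these 10 lists, in the order without input 1, input 2, masked TH59-DB 1, masked TH59-DB 2, TH59-DB 1 and TH59-DB 2, the medians relative to all models were 1.18, 1.23, 1.15, 2.36, 1.35 and 1.37 for nuclear lncRNAs. They were 1.57, 1.06, 1.93, 1.7, 1.43 and 1.48 for mitochondrial genes, and 0.37, 0.27, 0.30, -0.47, 0.59 and 0.43 for Zfp genes. Further values were 0.00, 0.01, 0.00, 0.56, 0.51 and 0.38 for lncRNA genes, and 0.00, 0.01, 0.00, 1.53, 0.73 and 0.38 for loci in no gene span. The next were -0.34, -1.99, -1.41, 0.26, -1.13 and -1.24 for snoRNAs, and -0.89, -0.58, -0.56, 0.43, -0.61 and -0.65 for ribosomal proteins. The others were -0.88, -0.95, -0.62, 0.28, -0.77 and -0.77 for histones, and -1.02, -0.90, -0.61, -0.06, -0.83 and -0.84 for translation factors. They were -1.15, -0.91, -0.84, 0.06, -0.84 and -0.85 for abundant cytoplasmic mRNAs. Without masked TH59-DB 2 the median of all tested models was -1.53, against -0.26 as reported, and the relative values of that setting are set against it.

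No shift was called for loci within 1 Mb (0 of 154 higher, median 0.25 above all models, unshifted mean -0.06, camera adjusted p = 0.0827) or within 3 Mb (0 of 313, 0.521). The same held for telomerase and shelterin (0.405, Terf2 3.69), snoRNA hosts (0.931, Snhg8 0.96), scaRNAs (0.931, Scarna6 -2.04), spliceosomal RNAs (0.237, Rnu1b1 -2.40) and small polymerase III RNAs (0.0763, Rny3 -3.68). It held for erythroid genes (0.263, Car2 -2.47, Ppox 1.33), secretory mRNAs (0.0516, Ssr4 -1.87), long genes (0.931, Lrp1b 5.76, Gphn -3.35), retained-intron mRNAs (0.419, Ccnl2 4.87) and antisense-named genes (0.431, Foxd2os 0.46). Of 2771 protein-coding genes 3 were higher, and 0 when adjusted over the list alone (camera adjusted p = 0.302). Relative to all models the medians of snoRNA hosts (0.02), scaRNAs (0.23), long genes (0.26) and antisense-named genes (0.01) were positive, while camera placed these lists below the rest. For retained-intron mRNAs the median was -0.10 and the mean 0.25. The 2 blood markers had a median of -1.38. Newly called with the preset correlation were small polymerase III RNAs without masked TH59-DB 1 or input 2, spliceosomal RNAs without input 2 and secretory mRNAs without TH59-DB 2. None of these was called with an estimated correlation. With 1 library left out, medians relative to all models ran from 0.00 (without input 1) to 1.53 (without masked TH59-DB 2) for loci within 1 Mb and 0.00 (without input 1) to 0.83 (without masked TH59-DB 2) for loci within 3 Mb. Further ones ran from 0.12 (without input 2) to 1.49 (without masked TH59-DB 2) for telomerase and shelterin and -0.62 (without input 2) to 0.90 (without masked TH59-DB 2) for snoRNA hosts. Others ran from -0.08 (without input 2) to 1.37 (without masked TH59-DB 2) for scaRNAs and -2.45 (without input 2) to 0.56 (without input 1) for spliceosomal RNAs. Those ran from -2.44 (without input 2) to -0.11 (without masked TH59-DB 2) for small polymerase III RNAs and -0.55 (without input 2) to -0.16 (without masked TH59-DB 2) for erythroid genes. Further ones ran from -0.66 (without input 2) to 0.28 (without masked TH59-DB 2) for secretory mRNAs and 0.00 (without input 1) to 1.53 (without masked TH59-DB 2) for long genes. Others ran from -0.02 (without input 1) to 0.89 (without masked TH59-DB 2) for retained-intron mRNAs and -2.98 (without masked TH59-DB 2) to 0.37 (without masked TH59-DB 1) for antisense-named genes. Those ran from -0.13 (without input 1) to 0.18 (without masked TH59-DB 2) for protein-coding genes. By fry no list moved, with adjusted p of at least 0.408.

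At an unadjusted p under 0.05, 208 models were higher and 159 lower, and DESeq2 called 101 higher and 20 lower. Library totals gave 90 higher and 18 lower, and totals without the 2 largest models 117 and 18. The median of all models was -0.26, and -0.08, 0.00 and 0.23 with DESeq2 size factors, library totals and totals without the 2 largest models. The count of 14, all higher, was 1413 without masked TH59-DB 2, with 409 higher and 1004 lower. It was 99 without masked TH59-DB 1 (69 and 30), 69 without TH59-DB 1 (all higher) and 64 without TH59-DB 2 (58 and 6).

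Both captures were compared with the same input libraries, which asks how alike their RNA was relative to the input. All 14 models higher in masked TH59-DB were among the 193 higher in TH59-DB, and so were 75 of the 76 models higher than masked TH59-DB. None of the 76 was among the 14. The 3 comparisons share libraries, so these overlaps were not tested against chance. The log2 fold changes of both captures over the input had a Pearson r of 0.595 across 5385 models (covariance 1.72). Simulated unchanged groups, drawn around the mean of these same input libraries, gave a mean r of 0.0600 and a range of 0.0238 to 0.0970. The input's own error cancels in that setting, so it cannot show how much of 0.595 came from the shared input. With a different input library for each capture r was 0.472 and 0.489.

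Whether a difference between TH59-DB and masked TH59-DB in library number 1 was seen again in number 2 was compared across models. Terc had log2 differences of 8.08 and 9.15, and the chromosome Y model from 90813197 had 10.00 and 10.95. Over all models the Pearson r was 0.246 and the Spearman rho 0.156, and models are not independent replicates. At least a doubling was seen in both numbers for 772 models (558 if independent), a halving in both for 169 (156), and opposite changes of that size for 687. By CPM, 84.8% of all models were higher and 15.2% lower in TH59-DB in library number 1. In number 2 the balance was the reverse, with 25.0% higher, 62.1% lower and 12.8% equal.

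**Figure D4:**
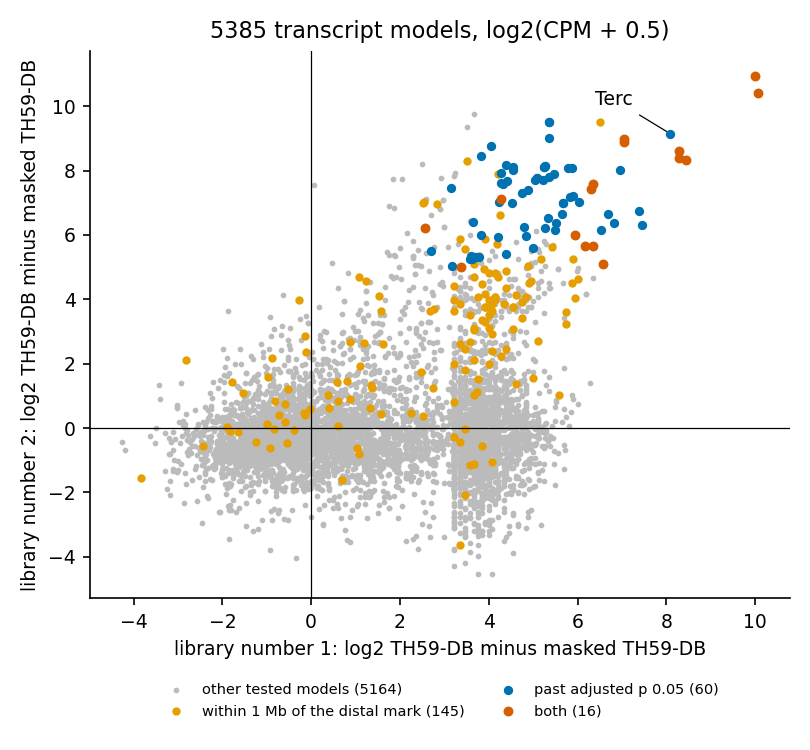
Log2 difference of TH59-DB and masked TH59-DB in library number 1 (x axis) and number 2 (y axis), 1 point per tested model, with models within 1 Mb of the distal mark and those past the threshold in colour. All 76 called models lay above 0 in both numbers, and the Pearson r over all 5385 was 0.246.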

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

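Every setting of the count within 1 Mb of the distal mark, library totals, totals without the 2 largest models and 1 model per overlapping cluster were chosen after seeing the data. Counts of models past the threshold are given in the order TH59-DB against masked TH59-DB, TH59-DB against input, masked TH59-DB against input (76, 195 and 14 as reported), followed by the first comparison within 1 Mb (16). They were 206, 312, 113 and 41 with no filter, 167, 252, 57 and 33 with DESeq2 size factors, and 267, 397, 121 and 58 with the DESeq2 Wald test. Only the groups compared gave 129, 497, 16 and 27, library totals 155, 230, 108 and 29, totals without the 2 largest models 161, 303, 135 and 26, and 1 model per overlapping cluster 50, 151, 8 and 10. The last tests fewer models, and for the other changes the cause was not tested. Without chromosome Y the count within 1 Mb was 8. At least 5 CPM in 2 libraries gave 56, 196, 14 and 13, and removal of structural RNA and mitochondrial models 89, 196, 14 and 18.

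Leaving out 1 library gave 32 to 1720, 102 to 756, 0 to 1413 and 8 to 94 models. The lowest counts came without TH59-DB 2 and, for masked TH59-DB against input, without input 1 or input 2, and all 4 highest without masked TH59-DB 2. The lone library left in a group is then assumed to vary like the other groups, and the cause was not tested. The 14, 13 and 10 list shifts of 23 became 6 to 14, 12 to 14 and 1 to 10. In the first comparison 7 were called without TH59-DB 1 and 6 without masked TH59-DB 2, and in the third 1 without masked TH59-DB 2. With an estimated correlation camera called 0 in each comparison (2, 2 and 0 at an unadjusted p under 0.05, and fry called 5, 4 and 0). Leaving out masked TH59-DB 1, it called loci within 1 Mb and protein-coding genes, with adjusted p = 0.0373 in the first comparison and 0.0431 in the second, and leaving out any other library it called 0.

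The deviations of same-numbered libraries from their group means correlated at 0.104, 0.0811 and -0.0239 across models. With 2 libraries a group these values cannot settle whether the numbers pair the samples. With the number as a block the counts were 191, 363, 106 and 36, and the list shifts 12, 13 and 13. The correlation of both captures over the shared input, 0.595, was 0.472 and 0.489 with a different input library for each capture and 0.603 with the stricter filter. The agreement of library numbers, 0.246, was 0.258 with the stricter filter, 0.326 after quantile normalization and 0.271 with library totals. Over the named models and their alternatives, 3945 values kept direction and side of the threshold, 442 newly passed, 75 no longer passed and 130 changed sign. Of the 130, 78 came from leaving out 1 library. None of these 58 results had passed as reported, and 1 passed after the change: Peak1os in TH59-DB against masked TH59-DB, without masked TH59-DB 2 (7.67, adjusted p = 0.00686). What caused the changes was not tested. At 1803723 to 3122558 reads a library and 2 libraries a group, 37.2% of simulated 16-fold changes were called. The planned pseudocounts and quantile normalization of the tests were for normalized values and were not run.

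In TH59-DB against masked TH59-DB, the sign changed with totals without the 2 largest models for Malat1 (-0.25), Snord15a (-0.0037), Rnu3a (-0.033), Rny3 (-0.12), mt-Rnr1 (-0.79), Rps14 (-0.15) and Rsf1os2 (-0.0059) and with DESeq2 size factors for the chromosome 17 ribosomal locus from 39842884 (0.037) and Peak1os (0.24). The same happened with the DESeq2 Wald test for the chromosome 17 ribosomal locus from 39842884 (0.037) and Peak1os (0.28) and with library totals for mt-Rnr1 (-0.52) and Rps14 (-0.15). So it did with a block for Peak1os (0.63) and with only the groups compared for Peak1os (0.013). In TH59-DB against input, the sign changed with a block for Rmrp (0.023) and with only the groups compared for Rmrp (0.050). The same happened with at least 5 CPM in 2 libraries for Rmrp (0.012) and with DESeq2 size factors for Rmrp (0.33). So it did with library totals for Rmrp (0.13) and Gapdh (-0.019) and with totals without the 2 largest models for Rmrp (0.16) and Gapdh (-0.052). Further changes came with the DESeq2 Wald test for Rmrp (0.33) and with no filter for Norad (-0.034). In masked TH59-DB against input, the sign changed with totals without the 2 largest models for Rn7sk (0.063), Rpph1 (0.25), Scarna9 (0.48), Rplp2 (0.31), H2ac6 (0.48), Zfpm1 (0.39), Pfn1 (0.43), Canx (0.46) and Srrm2 (0.29) and with a block for Snora65 (-0.11). The same happened with only the groups compared for Scarna9 (0.088), H2ac6 (0.068) and Canx (0.053) and with no filter for Scarna9 (0.043) and H2ac6 (0.00011). So it did with DESeq2 size factors for Scarna9 (0.085), H2ac6 (0.15), Zfpm1 (0.036), Pfn1 (0.067) and Canx (0.10) and with library totals for Scarna9 (0.35) and Canx (0.069). Further changes came with the DESeq2 Wald test for Scarna9 (0.078), H2ac6 (0.15), Zfpm1 (0.036), Pfn1 (0.067) and Canx (0.10).

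Leaving out 1 library, values in TH59-DB against masked TH59-DB ran from -0.12 to 0.86 for Malat1, -1.49 to 0.27 for Gata1, -1.10 to 0.012 for Actb, -0.60 to 0.12 for the chromosome 17 ribosomal locus from 39842884 and -3.03 to 4.32 for Terf2. Others ran from -0.29 to 6.76 for Snhg12, -0.20 to 0.58 for Rnu3a, -0.41 to 0.68 for Rny3, -2.15 to 1.85 for mt-Rnr1 and -0.75 to 5.79 for Rps14. Others ran from -0.37 to 2.40 for H2bc6, -1.49 to 0.44 for H2ac20, -3.50 to 0.21 for Eif4a1, -1.39 to 0.055 for Hsp90ab1 and -1.15 to 0.035 for Canx. Others ran from -6.27 to 0.036 for Ccnl2 and -1.04 to 7.67 for Peak1os. Leaving out 1 library, values in TH59-DB against input ran from -0.57 to 0.69 for Rmrp, -0.96 to 1.17 for Gata1, -0.65 to 0.81 for Gapdh, -0.77 to 0.012 for the chromosome 17 ribosomal locus from 39842884 and -0.17 to 0.18 for Norad. Others ran from -0.071 to 0.99 for Snhg8, -1.01 to 0.41 for Snord15a, -1.31 to 2.48 for Scarna6, -0.017 to 3.22 for Scarna9 and -0.089 to 2.88 for Rnu11. Others ran from -2.26 to 0.57 for Rnu3a, -4.32 to 0.23 for Rny3, -0.32 to 1.26 for ND6, -3.40 to 0.23 for mt-Rnr1 and -0.44 to 0.55 for Dnajb11. Others ran from -1.46 to 0.077 for Canx and -0.15 to 0.82 for Srrm2. Leaving out 1 library, values in masked TH59-DB against input ran from -0.64 to 0.22 for Rpph1, -3.22 to 2.60 for Ftl1-ps2, -0.54 to 2.25 for Zc3h7a, -0.58 to 0.26 for the chromosome 17 ribosomal locus from 39842884 and -2.35 to 5.05 for Terf2. Others ran from -1.27 to 0.81 for Snora65, -1.28 to 0.12 for Snord15a, -0.024 to 1.92 for Scarna17, -1.33 to 0.73 for Scarna9 and -2.22 to 0.73 for Rnu11. Others ran from -2.42 to 0.40 for Rnu3a, -4.40 to 0.15 for Rny3, -0.19 to 0.75 for Rpl3, -0.47 to 0.23 for Rplp2 and -0.91 to 0.65 for H2ac6. Others ran from -5.63 to 2.33 for Ppox, -0.38 to 0.093 for Zfpm1, -0.72 to 0.45 for Pfn1, -0.31 to 0.14 for Canx and -5.17 to 1.60 for Foxd2os.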

Other observations

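Several loci were named after their values were seen. A model of the Xkrx span (chromosome X, 134149579 to 134150503) had 310 CPM ± 196 in TH59-DB and 2.04 ± 0.735 in masked TH59-DB (SD, n = 2), a 152-fold ratio with a counting interval of 86.3 to 311 (log2 fold change 7.71, adjusted p = 0.0183). A model in the span of Esr1 (chromosome 10, 4614286 to 4614937), had 885 CPM ± 555 and 5.89 ± 2.44, a 150-fold ratio (7.63, 0.0252). Other loci were high in both captures. The model in the Plxnc1 span had 2037 CPM ± 534 in TH59-DB, 206 ± 178 in masked TH59-DB and 0.845 ± 0.700 in the input. TH59-DB over the input was 2410-fold there (pooled ratio 2300, counting interval 985 to 7085, adjusted p = 0.00330), and TH59-DB over masked TH59-DB did not pass (log2 fold change 3.30, adjusted p = 0.256). A locus in no gene span on chromosome 13 (116192889 to 116193000) had 5428 CPM ± 5188, 650 ± 17.8 and 0.853 ± 0.215 in the same order.

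Ribosomal protein genes together held 1.34% ± 0.509 of input reads, 0.849% ± 0.470 of masked TH59-DB and 0.363% ± 0.0284 of TH59-DB (SD, n = 2 each). The mitochondrial chromosome held 1.38% ± 0.280, 1.11% ± 1.17 and 0.626% ± 0.454 in that order. Nuclear loci in no gene span, the 3 largest left out, held 1.23% ± 0.787, 0.878% ± 0.170 and 6.69% ± 3.61, and loci within 1 Mb of a distal mark 0.152% ± 0.0514, 0.197% ± 0.0460 and 2.56% ± 1.76. In masked TH59-DB 1, 4341 models had 0 reads, against 2237 on average when masked TH59-DB 2 was thinned at random to the same number of reads outside the 2 largest models. Thinning covers counting error only, and how much separate libraries of this group differ was not known.

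All tests of the 3 patterns below were chosen after the result was seen. Of 291 loci within 1 Mb of the distal mark 154 passed the read filter, and 12 of these were higher in TH59-DB. As a list the tested loci lay above the rest with a preset correlation (camera adjusted p = 4.48e-21) but not with an estimated one (0.346). The models might have been chosen for their reads in TH59-DB 1, but in library number 2 alone 89.2% of 130 loci within 100 kb had a higher CPM (95% exact interval 82.6% to 94.0%), against 22.5% over 10 Mb away, and 89.0% of 118 without chromosome Y (81.9% to 94.0%). With 4341 models at 0 reads in masked TH59-DB 1, library number 1 cannot decide this. The share without chromosome Y argues against that chromosome as the whole cause. The value in number 2 cannot exclude the choice of models, since no set of similar loci far from the marks was compared. In that number the median log2 difference was 1.43 over tested loci in no gene span and -0.42 over protein-coding genes. The intervals also treat neighbouring loci as independent. DNA of the chromosome ends carried through the capture cannot be told apart from RNA: 55.4% of these loci (72) had 0 reads in both inputs, strands were not told apart, and the labels name no DNase step. Capture of RNA at chromosome ends by the telomere-directed probe also stays open.

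More models were higher in TH59-DB in library number 1 (84.8%) than in number 2 (25.0%), where 62.1% were lower. A choice of models by their reads in TH59-DB 1 may be the cause: 99.3% of models had at least 10 reads there, against 30.3% to 58.7% in the other libraries. Of 1586 models at 0 in input 1 and masked TH59-DB 1, 892 were also at 0 in TH59-DB 2. Totals without the 2 largest models gave 76.9% and 23.6%. These cannot decide whether a few models taking most reads of masked TH59-DB 1 was the cause. The 4341 models at 0 reads there had at least 5 in TH59-DB 1, so they stay higher in number 1 under any totals. No biological explanation was tested.

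The 9 loci called in masked TH59-DB against input were also higher in TH59-DB against input. Reads of TH59-DB libraries might have leaked into the masked libraries. The lowest ratio of masked TH59-DB to TH59-DB over these loci was 8.83% in library number 2, while Terc, abundant in TH59-DB, had 0.342% (upper limit 0.402%), and in number 1 the values were 8.97% and 0.246% (0.289%). A leak of one share therefore did not account for them. RNA or DNA held by both probes stays open and was not tested.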
